A study of Homo sapiens with 8 samples.

How the data were processed

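The series holds 8 human small RNA libraries: cell RNA and EV RNA of HepG2 and of LX2, each line grown alone or in a transwell beside the other. Replicate numbers stand for the culture (1, HepG2 alone; 2, LX2 alone; 3, HepG2 with LX2; 4, LX2 with HepG2), so each culture has a cell library and an EV library and no condition is repeated. Per the labels, cell RNA was extracted with TRIzol and EV RNA with a precipitation reagent and its own column kit, and all libraries were made with the same small RNA kit. Whether the medium held serum, and the aligner and its settings, are not given in the sources used here. The submitters' processing notes name the genome build GRCh37.

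The deposited tables give, per library, a raw read count for each of 2573 miRNAs and each of 7483 other small RNAs (2314 piRNA, 2066 snRNA, 1613 snoRNA, 865 Y RNA and 625 tRNA entries), the reads of 138 putative miRNAs and a summary of reads per category. In the table of other small RNAs 3 entries name no feature. Of the lines for miRNA counts, 5 are empty of values, and between 1.23% and 5.57% of the miRNA reads of the summary are missing from that table. The deposited tables labelled TPM hold a score: for every library 100% of the entries equal the count, scaled to a common total, of the miRNA, small RNA, putative miRNA and other genome-mapped reads together, with decimals removed. The authors also deposited tables of log2 fold changes between cell and EV libraries, each with a p-value and a false discovery rate, which were compared with the values computed here and not used otherwise. Raw counts were the input of all tests here, and the TPM score entered 1 alternative.

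Total reads per library ranged from 12421094 (cell RNA of LX2 alone) to 21230298 (EV RNA of HepG2 with LX2). The miRNA table held 2343737 to 3782030 counts per cell library and 55861 to 142539 per EV library, and for other small RNAs they were 1585463 to 4518653 and 243075 to 1014083. Counting intervals are exact 95% (Clopper-Pearson) intervals, and 3 counts over a group of libraries is the floor for a group without counts. The libraries carry no molecular identifiers, so intervals and floors cover counting error only.

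Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Features were kept by filterByExpr with compartment as the group (407 miRNAs and 743 other small RNAs, each table with its own TMM factors) and tested with the edgeR quasi-likelihood F test, with Benjamini-Hochberg adjustment and a threshold of 0.05. EV RNA was compared with cell RNA with culture as a block (3 residual degrees of freedom). HepG2 and LX2, the interaction of line and compartment, and co-culture were tested in 1 model with 4 line-by-compartment means and a co-culture term (3 residual degrees of freedom), in which the spread comes from how the co-culture difference varies over lines and compartments. Standard errors were obtained as the size of the log2 fold change divided by the square root of F. That a cell and an EV library come from 1 culture was taken from the labels of line and co-culture alone. Deviations from the mean of the compartment correlated between the libraries of a culture with r = 0.529 to 0.665 across miRNAs and 0.224 to 0.392 across other small RNAs, which are not independent replicates. Between a cell library and the EV library of the other culture of its line they gave 0.507 to 0.722 and 0.260 to 0.475, so the values reflect the line and do not test the pairing.

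The shares of RNA classes were compared with exact permutation tests (70 arrangements of the 8 libraries, which do not keep the pairs). The 18 miRNA lists were fixed before the data were examined: hepatocyte and epithelial, mesenchymal and stellate, blood and serum, muscle and neural, fibrosis, let-7, miR-17-92 with paralogs, miR-29, miR-30, miR-34 and miR-449, miR-181, miR-210, miR-320, 14q32, C19MC, miR-371 and miR-302, Xq27, and miRNAs that overlap structural RNA. Lists with 5 or more tested members were tested with camera on log CPM (prior count 2, preset correlation 0.01), with an estimated correlation as an alternative and fry as another test. The ratio of co-culture to monoculture within a line and compartment was computed from 1 library against 1 with TMM scaling and no test. miRNAs specific to the partner line (16-fold higher in it and at least 50 CPM, chosen in the other compartment of the monocultures) were compared with 10000 random lists, each member drawn from the 30 features nearest in level.

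Features were named by a rule fixed before the data were examined: adjusted p under 0.05, a mean of at least 50 CPM on 1 side and the same direction in every matched pair, of which the 12 largest rises and 12 largest falls, together with the 8 most abundant features of each compartment and any member of the fixed lists. For 1 library against 1 the 5 largest ratios each way were named among miRNAs with at least 100 counts in 1 of both libraries. The tests were tried on simulated data before use. In it the paired miRNA test found 13 of 50 features changed 4-fold and 38 of 50 changed 16-fold, with 3 false calls. Alternatives were DESeq2 size factors, total counts, library sizes from both tables, the DESeq2 Wald test, limma on log2 of the TPM score plus 1, no filter, a filter of 50 counts in 4 libraries, no block, subsets of the cultures, each library or culture left out, and 8-fold and 20 CPM for partner-specific miRNAs. Added after the data were seen were the tests of other small RNAs between the lines, gene copies summed per family under 3 scalings, the EV comparison without the blood and muscle lists, and fry. Putative miRNAs, which have no annotation, entered no comparison.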

Results

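The series concerns RNA that liver tumour cells and liver stromal cells release in extracellular vesicles (EVs), and its possible use as a marker of the tumour environment. Small RNA was sequenced from HepG2, a hepatocellular carcinoma line, and from LX2, a human hepatic stellate line, each grown alone or across a transwell membrane from the other line. Every one of these 4 cultures gave 1 library of cell RNA and 1 library of EV RNA, so the 8 libraries hold 4 matched pairs and no repeat of any condition. Nothing in the labels says that the cultures were repeated, so all p-values measure only the spread between these libraries. Cell RNA and EV RNA were also extracted by different methods, so compartment and extraction cannot be told apart here. EV libraries of co-cultures are named by the line of the label, and vesicles of the partner line in them cannot be told apart.

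EV RNA held a different mixture of RNA classes from cell RNA. Transfer RNA (tRNA) made up 66.0% ± 9.89 of the miRNA and other small RNA counts in EV RNA and 30.4% ± 19.3 in cell RNA (mean ± SD, n = 4 libraries each). Spliceosomal small nuclear RNA (snRNA) made up 11.6% ± 7.11 against 0.269% ± 0.135, and piRNA entries made up 0.113% ± 0.0225 against 0.0549% ± 0.0277. MicroRNA (miRNA) was lower in EV RNA, at 15.7% ± 5.11 against 52.1% ± 12.5, as was small nucleolar RNA (snoRNA), which guides modification of ribosomal RNA, at 2.23% ± 0.640 against 15.4% ± 6.50. Each of these 5 classes differed in the same direction in 4 of 4 cultures (two-sided exact permutation test that leaves the pairs aside, p = 0.0286, the smallest that 4 against 4 libraries can give, adjusted p = 0.0333 over 7 measures). For tRNA the gap was small in HepG2 beside LX2, with 57.6% in EV RNA and 56.2% in cell RNA. Y RNA, a class of short non-coding RNAs bound by the Ro60 protein, made up 4.35% ± 1.42 of EV RNA and 1.71% ± 1.80 of cell RNA and was higher in 3 of 4 cultures (exact permutation test, p = 0.0857, adjusted p = 0.0857). Reads that found no place in the genome made up 83.5% ± 4.14 of EV libraries and 27.8% ± 0.382 of cell libraries (exact permutation test, p = 0.0286, adjusted p = 0.0333). Measured against all mapped reads instead, the tRNA difference shrank to 1.29 points (exact permutation test, p = 0.857) and the piRNA difference to 0.000347 points (exact permutation test, p = 1).

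**Figure D1:**
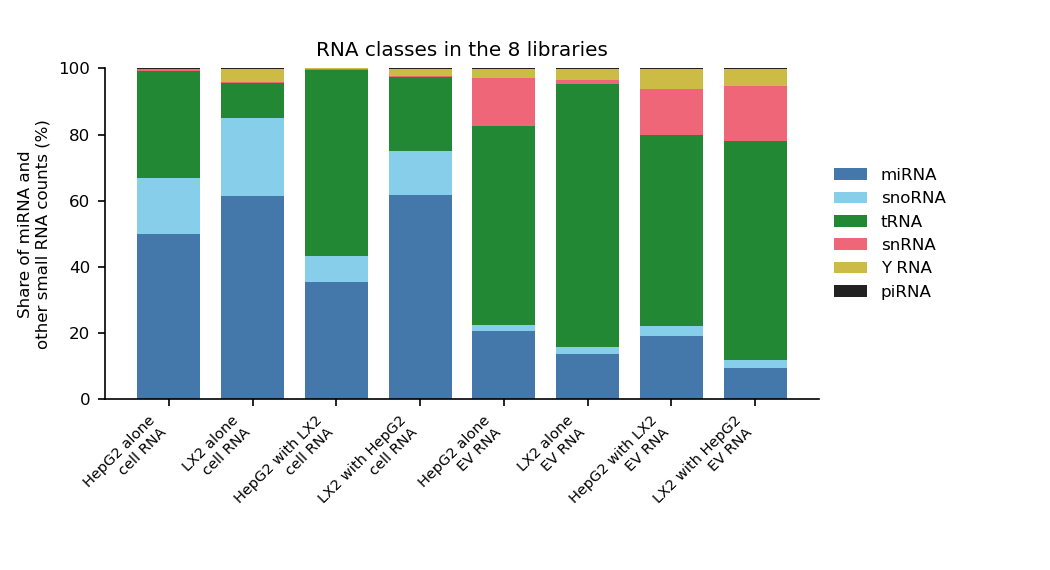
Share of each RNA class (vertical axis, % of the miRNA and other small RNA counts of a library) in the 4 cell RNA and 4 EV RNA libraries (horizontal axis); each bar is 1 library and starts at 0. miRNA took 35.3% to 61.7% of the cell libraries and 9.53% to 20.7% of the EV libraries. The EV library of LX2 grown alone held 1.04% snRNA where the other 3 held 14.2% to 16.6%.

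Among miRNAs, miR-21-5p, which is abundant in many cancers, took the largest mean share in both compartments, with 39.3% ± 18.5 of cell miRNA counts and 17.3% ± 6.07 of EV miRNA counts (mean ± SD, n = 4). It did not lead in cell RNA of LX2 grown alone, where it took 12.4% and miR-100-5p 24.0%, nor in EV RNA of HepG2 grown alone, where it took 10.1%, the liver miRNA miR-122-5p 28.6% and miR-148a-3p 11.7%. The mean of miR-122-5p in EV RNA, 9.96% ± 12.8, was drawn up by that library. EV RNA of LX2 alone held 7.84%, against 0.00188% in its cells. EV RNA of HepG2 beside LX2 held 1.60% and that of LX2 beside HepG2 1.80%. The hepatocyte-enriched miR-148a-3p took 9.59% ± 7.02 of EV counts and 8.55% ± 9.92 of cell counts. miR-100-5p took 3.33% ± 3.48 and 8.93% ± 11.5, and miR-92a-3p of the miR-17-92 cluster 5.43% ± 1.37 and 2.53% ± 1.11. In the table of other small RNAs the most abundant entries of EV RNA were copies of the glutamate tRNA with anticodon CTC. The copy named tRNA77-GluCTC on chromosome 6 took 7.49% ± 0.926 of EV counts and 2.82% ± 0.837 of cell counts. In cell RNA the snoRNA SNORD49A had a larger mean share than that copy, at 3.47% ± 1.99, which came from the LX2 libraries. It took 5.71% in LX2 alone and 4.32% beside HepG2, where the copy took 2.06% and 2.29%. In HepG2 cells it took less than the copy, 2.75% against 3.01% alone and 1.10% against 3.92% beside LX2. Reads that fit several tRNA copies cannot be assigned to 1 of them, so values of single copies are uncertain.

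Among the miRNAs called between EV and cell RNA, those of blood cells led the rise in EV RNA. Rises of this size were not confined to them. The liver miRNA miR-122-5p, not called here, stood at 101138 ± 157650 CPM in EV RNA. The authors list it among their calls, at -10.27 on the log2 scale for cell over EV RNA (-10.29 for miR-451a). The erythroid miR-451a stood at 1164 ± 604 CPM (counts scaled to a common library total) in EV RNA and 1.60 ± 2.61 CPM in cell RNA (mean ± SD, n = 4; log2 fold change 10.24, SE 1.21, adjusted p = 0.00865 by edgeR). miR-486-5p, of red cells and muscle, stood at 7175 ± 7060 against 9.35 ± 8.48 CPM (log2 fold change 9.69, SE 1.06). miR-126-3p, of endothelial cells and platelets, stood at 6801 ± 2415 against 199 ± 135 CPM (5.32, SE 0.860). miR-142-5p, of white blood cells, rose by 7.15 on the log2 scale (SE 1.01). The erythroid miR-144-3p had 1 count in the 4 cell libraries together, which makes its EV to cell ratio 1859 (95% counting interval 327.6 to 74031). The lymphocyte miR-150-5p had 2, a ratio of 592 (159 to 4976). The myeloid miR-223-5p and the erythroid miR-144-5p had no count in any cell library and were at least 359.9-fold and at least 269.9-fold higher in EV RNA. Outside blood, miR-1246, whose sequence lies within U2 snRNA, rose from 66.7 ± 25.7 to 5911 ± 3610 CPM (6.38, SE 0.708). Likewise miR-1468-5p rose by 5.25 (SE 1.09) and miR-320c by 4.02 (SE 0.771).

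**Figure D2:**
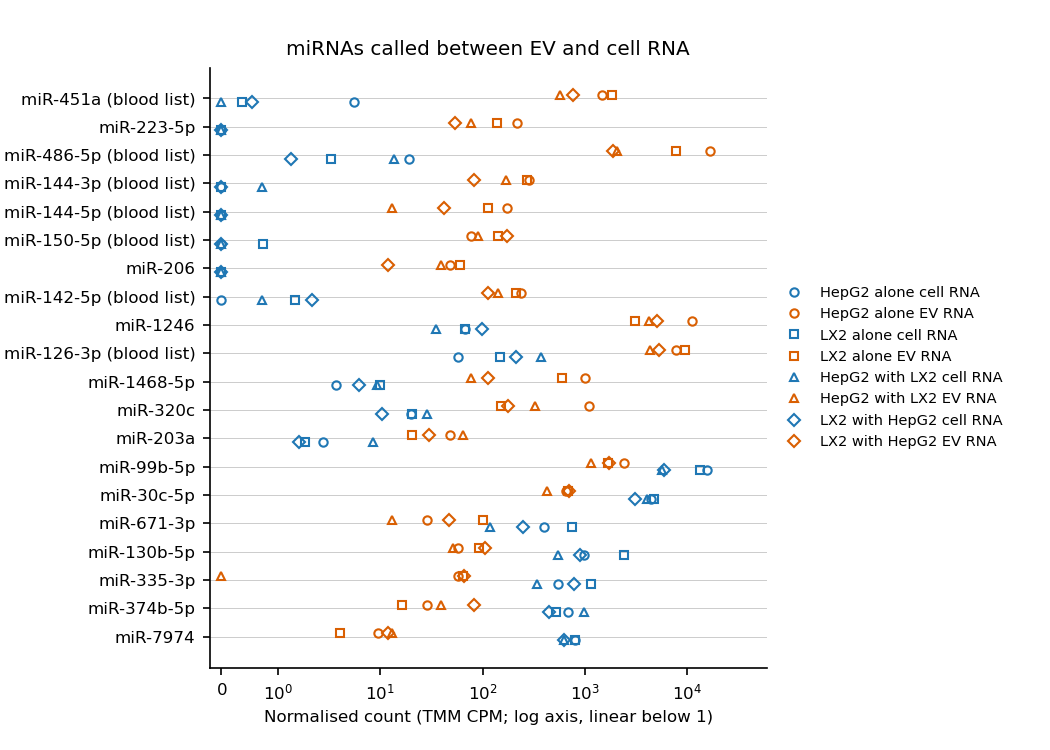
Normalised counts (horizontal axis, CPM after TMM scaling, logarithmic above 1 and linear below) of the 20 miRNAs called between EV RNA and cell RNA (vertical axis, ordered by fold change, 13 higher and 7 lower in EV RNA). Each symbol is 1 library, EV RNA in orange and cell RNA in blue, and the shape gives the culture. The EV symbols of miR-451a lie between 571 and 1866 CPM and its cell symbols at 5.50 CPM or less.

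The 7 miRNAs that fell were abundant in cells. miR-7974 stood at 9.61 ± 3.97 CPM in EV RNA and 712 ± 102 CPM in cell RNA (log2 fold change -6.30, SE 0.777, adjusted p = 0.00865 by edgeR). miR-30c-5p stood at 616 ± 127 against 4100.4 ± 728 CPM (-2.74, SE 0.536). miR-374b-5p fell by 4.14, miR-335-3p by 4.13, miR-130b-5p by 3.83, miR-671-3p by 3.02 and miR-99b-5p by 2.44 on the log2 scale. In all, 20 of 407 tested miRNAs passed an adjusted p of 0.05 (13 higher, 7 lower in EV RNA, and 123 at an unadjusted p under 0.05).

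Of 18 miRNA lists fixed in advance, 9 had 5 or more tested members. In the blood and serum list 7 of 10 tested members rose (9 adjusted over the list alone), with a median log2 fold change of 8.29 (7.51 from pooled counts with absent groups set to the floor of 3 counts; camera adjusted p = 1.04e-10, adjusted p = 0.287 with an estimated correlation). Its other members were miR-142-3p (7.72), miR-126-5p (5.16) and miR-16-5p (0.64), which is common outside blood as well and turned negative with limma (-1.36). The 14q32 list, miRNAs of the imprinted DLK1-DIO3 region, had no called member among 31 (adjusted p = 0.0103, adjusted p = 0.776 with an estimated correlation). Its median was 1.81 in the fit but -0.76 in pooled counts, because the lines differed in direction. The hepatocyte and epithelial list had 1 called member of 13, miR-203a (3.60), and 2 higher and 1 lower adjusted over the list alone, with a median of 2.30 in the fit and -0.40 in pooled counts (adjusted p = 0.0157, adjusted p = 0.740 with an estimated correlation). In the miR-320 family 1 of 4 members rose (4 adjusted over the list alone). In the muscle and neural list it was 1 of 3 (2 adjusted over the list alone), namely miR-206, which had no cell count and was at least 125-fold higher. In the list of miRNAs that overlap structural RNA 1 of 7 rose, miR-1246 (2 higher and 2 lower adjusted over the list alone; adjusted p = 0.346). In the miR-30 family 1 of 5 members fell, miR-30c-5p (adjusted p = 0.397). No member was called in the mesenchymal and stellate list (15 tested, adjusted p = 0.0984), the let-7 family (9, adjusted p = 0.608), the miR-17-92 cluster with its paralogs (10, adjusted p = 0.947), the fibrosis list (19, adjusted p = 0.567), or the smaller miR-29 (3), miR-34 (3), miR-181 (3), Xq27 (3), C19MC (1), miR-371 and miR-302 (1) and miR-210 (1) lists, where miR-210 was lower adjusted over the list alone. The list counts depended on the scaling. With total counts 9 members rose in the blood list, 4 in the miR-320 family, 3 in the hepatocyte, 2 each in the mesenchymal and structural RNA lists and 1 in the fibrosis list, and none fell in the miR-30 family. With library sizes from both tables none rose in the miR-320 family and 9 in the blood list, 2 rose and 1 fell in the hepatocyte list, 1 rose and 2 fell in the structural RNA and the fibrosis lists, and 3 fell in the 14q32 list and 1 each in the miR-34, miR-210 and Xq27 lists. With DESeq2 size factors 6 rose in the blood list, 2 in the miR-320 family and none in the muscle and neural list. The count of 20 fell to 0 without LX2 grown alone and to between 7 and 9 without each other culture, to 2 without the blood and muscle lists, and to 0 within the monocultures or within the co-cultures. It was 116 within HepG2, 78 within LX2 and 36 without pairing by culture. Scaling to total miRNA counts gave 30 higher and 3 lower (median of all miRNAs moved by 0.85 on the log2 scale), and to the sum of both 16 and 72 (moved by -1.01), and DESeq2 60 and 61 (moved by 0.34).

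Among the other small RNAs, spliceosomal RNAs rose and box C/D snoRNAs fell in EV RNA. RNU11, the U11 RNA of the minor spliceosome (chromosome 1, 28975112 to 28975245, GRCh37), stood at 64336 ± 49015 CPM in EV RNA and 61.4 ± 23.4 CPM in cell RNA (log2 fold change 9.35, SE 1.49, adjusted p = 3.18e-05 by edgeR). SCARNA16, a Cajal body RNA, rose by 7.23 (SE 1.03), from 30.2 ± 20.3 to 4530.1 ± 2234 CPM. Of the copies of U1, U1.90 rose by 7.93, RNU1-11P by 7.16, U1.77 by 7.11, U1.17 by 7.01, RNU1-13P by 6.96 and RNU1-16P by 6.85, and of those of U2, U2.14 rose by 6.93. The piRNA entries uc021trw.1 and uc002gxe.2 rose by 8.96 and 8.47. SNORD12C (chromosome 20, 47895477 to 47895565) had 21 counts in the 4 EV libraries and 25766 in the 4 cell libraries, at 1519.9 ± 308 CPM (log2 fold change -7.57, SE 1.09, adjusted p = 1.88e-05). SNORD49A (chromosome 17, 16343350 to 16343420), abundant in cells, stood at 198 ± 170 against 18234 ± 4333 CPM (-6.84, SE 1.11). SNORD12 fell by 7.20, SNORD101 by 7.08, SNORD70 by 6.95, SNORD81 by 6.87, SNORD2.2 by 6.80 and SNORD59A by 6.63, and the piRNA entry uc010vxp.1 by 6.69. With few counts in EV RNA, the EV to cell ratio was 0.00859 (95% counting interval 0.00177 to 0.0251) for SNORD88B, 0.00710 (0.000859 to 0.0257) for SNORD19B.1 and 0.00604 (0.000153 to 0.0337) for SNORD121B.

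By family, 34 of 35 tested U1 copies and 19 of 21 U2 copies rose, and 119 of 182 box C/D snoRNAs fell while 14 rose (median log2 fold change -3.30). The EV library of LX2 alone had much less of the spliceosomal RNA, with 1.04% snRNA against 15.1% ± 1.32 in the other EV libraries. Box H/ACA snoRNAs, which guide pseudouridylation, fell in 15 of 39 cases and rose in 4. With scaling to total counts 137 box C/D snoRNAs fell and 3 rose, and 25 box H/ACA snoRNAs fell and 1 rose (with DESeq2 size factors 129 and 7, and 20 and 3). Among tRNA genes 13 of 14 for aspartate, 12 of 17 for glutamate and 6 of 26 for lysine rose, while 7 of 19 for glutamine, 8 of 22 for arginine, 4 of 18 for methionine and 3 of 20 for leucine fell. Of 31 for glycine 1 rose and 4 fell, and 0 rose and 11 fell with total counts. With scaling to total counts 1 for aspartate and 6 for glutamate rose, 6 for lysine rose and 4 fell, and 19 for glutamine, 15 for arginine, 18 for methionine and 16 for leucine fell; with DESeq2 size factors 19 for glutamine fell too. Y RNA entries rose in 53 of 126 cases with a median of 1.46, but with scaling to total counts 12 rose, 8 fell and the median was -0.01. Since such copies share reads, they were also summed per family: U1 rose by 7.14 (SE 1.43, adjusted p = 0.00274 by edgeR), U2 by 6.25 (SE 0.892), lysine tRNA with anticodon TTT by 4.88 (SE 0.724), Y RNA by 4.23 (SE 1.13) and aspartate tRNA with anticodon GTC by 4.15 (SE 0.856). Glutamate tRNA with anticodon CTC, at 4.26 (SE 1.64), did not pass (adjusted p = 0.0501). These sums depended on the scaling: with total counts, which moved the median of the summed table by -2.98, U1 (4.47), U2 (3.32) and lysine tRNA (1.95) still passed, and Y RNA (1.34, adjusted p = 0.268), aspartate tRNA (1.19, adjusted p = 0.0722) and glutamate tRNA (1.26, adjusted p = 0.0673) did not. With DESeq2 size factors all 6 passed, glutamate tRNA with 3.76 (adjusted p = 0.0216). In all, 337 of 743 tested small RNAs passed (167 higher, 170 lower, and 388 at an unadjusted p under 0.05). Scaling to total counts gave 79 higher and 289 lower (median of all moved by -1.53), and DESeq2 size factors 143 and 221 (moved by -0.58). The monocultures alone gave 146, no filter 564, and families summed to 1 entry 169 of 316.

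In cell RNA the lines differed by miRNAs of epithelium and liver on one side and of the 14q32 region on the other. miR-148a-3p stood at 333581 ± 85382 CPM in HepG2 and 54.8 ± 32.7 CPM in LX2 (mean ± SD, n = 2 libraries each; log2 fold change 12.65, SE 0.994, adjusted p = 1.98e-10 by edgeR). miR-224-5p stood at 5777 ± 1838 against 0.870 ± 0.851 CPM (12.64, SE 1.17). The epithelial miR-200b-3p had 3 counts in LX2 cells, a ratio of 29904 (95% counting interval 10232 to 145016). Its relatives miR-200a-3p, miR-200a-5p, miR-429 and miR-200b-5p had none and were at least 3893-fold, 3121-fold, 859.5-fold and 325-fold higher in HepG2. miR-483-3p and miR-483-5p, encoded within the IGF2 gene, were at least 1821-fold and 669-fold higher, and miR-1269b, miR-452-5p and miR-618 at least 2305-fold, 1017-fold and 473-fold. miR-493-5p stood at 9.36 ± 6.20 CPM in HepG2 and 10503 ± 4348 CPM in LX2 (-10.18, SE 0.903). miR-127-3p stood at 1.73 ± 1.44 against 3891 ± 1203 CPM (-11.18, SE 1.03), and miR-155-5p, an inflammatory miRNA, at 6.21 ± 6.77 against 6876 ± 747 CPM (-10.20, SE 0.990). miR-2682-5p, miR-767-5p, miR-409-5p, miR-503-5p, miR-34b-3p, miR-433-3p and miR-369-5p had no count in HepG2 cells and were at least 698-fold, 327.5-fold, 315-fold, 165-fold, 138-fold, 110.0-fold and 72.2-fold lower there than in LX2. miR-105-5p had 1 count in HepG2 cells, a ratio of 0.000542 (1.37e-05 to 0.00302), and miR-125b-1-3p 2, a ratio of 0.000765 (9.26e-05 to 0.00276).

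By list, all 31 tested 14q32 miRNAs were lower in HepG2 cells (median -7.79, and -7.07 from pooled counts with absent groups at the floor; camera adjusted p = 7.75e-16, adjusted p = 0.126 with an estimated correlation). Among them were miR-409-3p (-9.22, SE 0.859) and miR-381-3p (-7.65, SE 0.796). In the hepatocyte and epithelial list 12 of 13 were higher (median 9.98, and 9.06 at the floor; adjusted p = 2.42e-07, adjusted p = 0.233 with an estimated correlation). They included miR-192-5p (6.16, SE 0.801), miR-194-5p (5.74, SE 0.796) and miR-122-5p (9.98, SE 1.59), and miR-203a (1.62) did not pass. The difference in miR-122-5p was far larger between the co-cultures than between the monocultures. In the co-cultures it took 0.474% of miRNA counts in HepG2 cells and 0.000317% in LX2 cells. In the monocultures these were 0.0104% and 0.00188%. The mesenchymal and stellate list moved both ways, with 6 members lower, such as miR-100-5p (-8.90, SE 0.844) and miR-34c-5p (-7.30, SE 1.02), and 3 higher, miR-146a-5p (4.26), miR-199b-5p (6.73) and miR-143-3p (1.64). In the let-7 family 5 of 9 were lower, led by let-7b-5p (-4.63). In the Xq27 list 3 of 3 were lower, and in the miR-34 list miR-34a-5p was higher (5.23) while miR-34b-3p and miR-34c-5p were lower. The miR-30 family had 3 of 5 higher and miR-30a-5p lower (-5.04), and the miR-17-92 list 3 of 10 higher (1 adjusted over the list alone). The fibrosis list had 8 higher and 3 lower of 19, and the stem cell miRNA miR-372-3p was at least 134-fold higher. These list counts depended on the scaling. With total counts and with library sizes from both tables no miR-30 member was higher and 1 miR-17-92 member was, with 2 lower in the latter. The fibrosis list then had 6 higher and 6 lower, and 5 higher and 7 lower, and let-7 had 8 and 9 lower. In the mesenchymal and stellate list 2 were higher and 10 lower under either scaling. Of 407 miRNAs 204 passed (93 higher and 111 lower in HepG2, and 220 at an unadjusted p under 0.05). With library sizes from both tables the split was 52 and 179 and with total counts 61 and 146, and the count fell to between 91 and 118 without each cell RNA library and to 84 under the stricter filter.

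snoRNAs of 2 imprinted regions also differed between the lines in cell RNA, in opposite directions. All 11 tested snoRNAs of the 14q32 region were lower in HepG2 (median -10.55, and -10.16 at the floor). Of them SNORD114-9 (chromosome 14, 101432366 to 101432437) fell from 857 ± 20.7 CPM in LX2 to 0.539 ± 0.396 CPM (n = 2 each; -10.55, SE 0.897, adjusted p = 0.000583 by edgeR), with SNORD114-26 at -8.06 and SNORD114-22 at -7.67. SNORD113-8, SNORD112 and SNORD113-5 had no count in HepG2 and were at least 1147-fold, 348-fold and 224-fold lower, and SNORD123 of chromosome 5 at least 1407-fold. All 16 tested snoRNAs of the Prader-Willi region of 15q11, copies of SNORD116, were higher in HepG2, with a median of 9.46 in the fit and 6.63 at the floor. Y RNA entries were lower in 116 of 126 cases (median -3.16) and methionine tRNA genes higher in 16 of 18 (median 2.11), but in 4 of 18 with total counts (median 1.06) and 10 of 18 with DESeq2 size factors. Among single entries U2.35 was higher by 6.05 (SE 0.743), the selenocysteine tRNA gene tRNA1-SeCTCA by 5.25 (SE 0.804), tRNA22-MetCAT by 5.02 (SE 0.638), tRNA10-MetCAT by 4.998 (SE 0.675), U1.76 by 4.25 and tRNA6-ValTAC by 3.64. Of 743 small RNAs 208 passed (74 higher and 134 lower, and 291 at an unadjusted p under 0.05). Of the 134 lower ones 116 were Y RNA entries, copies that share reads. Copies were not summed per family for this comparison, so these counts are not numbers of independent differences. There was a split of 35 and 193 under total counts, 462 without a filter, 94 under the stricter filter, and 110 and 121 without the cell RNA library of HepG2 or LX2 grown alone.

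In EV RNA the same groups separated the lines by less. miR-200b-3p stood at 1366 ± 325 CPM in HepG2 EVs and 104 ± 78.9 CPM in LX2 EVs (n = 2 libraries each; log2 fold change 3.79, SE 0.723, adjusted p = 0.00233 by edgeR). miR-200a-3p stood at 1041 ± 418 against 138 ± 166 CPM (3.35, SE 0.818), miR-192-5p was higher by 3.33 (SE 0.706) and miR-148a-3p by 2.51 (SE 0.650). miR-483-5p was higher by 5.05 (SE 1.38), miR-1269b by 3.94, miR-148a-5p by 3.59, miR-200a-5p by 3.48, miR-429 by 3.38 and miR-483-3p by 3.37. Lower in HepG2 EVs were miR-34c-5p, at 37.2 ± 39.1 against 962 ± 67.8 CPM (-4.82, SE 0.985), miR-125b-1-3p (-4.50, SE 0.987), miR-155-5p (-4.26, SE 0.772), miR-370-3p (-3.81, SE 0.835), miR-100-5p (-3.74, SE 0.669) and miR-134-5p (-3.49, SE 0.723). miR-767-5p, miR-891a-5p, miR-125b-2-3p, miR-31-5p, miR-221-5p, miR-30c-2-3p and miR-1262 had no count in HepG2 EVs and were at least 10.5-fold, 7.01-fold, 5.84-fold, 5.26-fold, 5.11-fold, 4.96-fold and 4.38-fold lower. With few counts on one side, the HepG2 to LX2 ratio was 36.5 (95% counting interval 9.32 to 315) for miR-6715a-3p, 28.5 (7.12 to 249) for miR-3118, 22.8 (3.25 to 991) for miR-194-3p, 17.1 (3.98 to 154) for miR-548k, 0.0224 (0.00269 to 0.0819) for miR-105-5p, 0.0442 (0.00901 to 0.132) for miR-654-3p and 0.0457 for miR-196a-5p. In the hepatocyte and epithelial list 8 of 13 members were higher in HepG2 EVs (10 adjusted over the list alone; median 3.33, and 2.54 at the floor; camera adjusted p = 4.37e-06, adjusted p = 0.379 with an estimated correlation). In the 14q32 list 6 of 31 were lower (8 adjusted over the list alone, 14 with total counts; median -1.81, and -1.28 at the floor; adjusted p = 0.000108, adjusted p = 0.379 with an estimated correlation). The mesenchymal and stellate list had 4 members lower and miR-146a-5p higher (1.98), and no member of the blood list passed. Of 407 miRNAs 52 passed (23 higher, 29 lower, 107 at an unadjusted p under 0.05), 1 without the EV library of HepG2 grown alone, 28 without that of LX2 grown alone and 4 from the 4 EV libraries by themselves. No other small RNA passed by edgeR (117 at an unadjusted p under 0.05), while DESeq2 called 31 and limma 122.

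**Figure D3:**
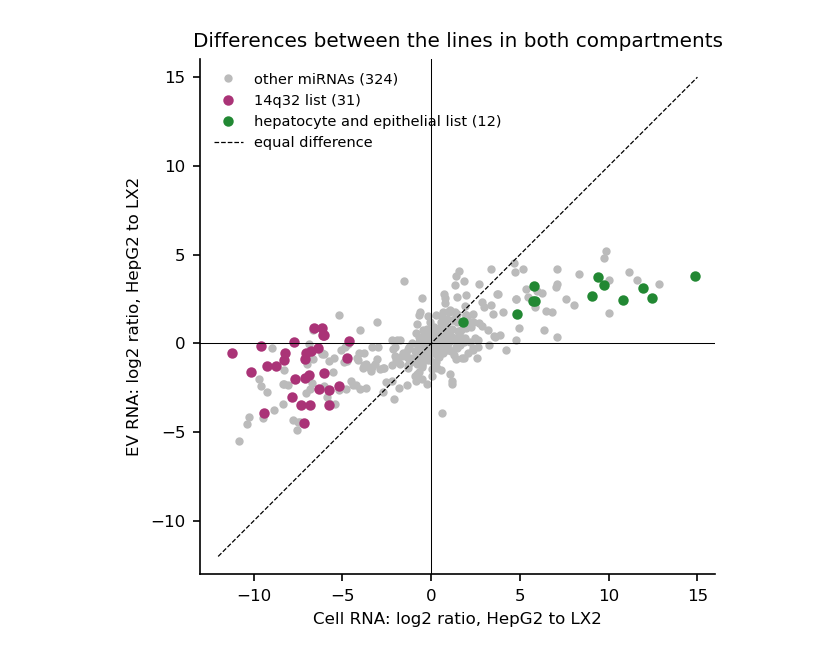
Ratio of HepG2 to LX2 in cell RNA (horizontal axis, log2) and in EV RNA (vertical axis, log2) from counts pooled over the 2 libraries of each line, with 3 counts in place of a group without any; each point is 1 of the tested miRNAs with more than 3 counts in both compartments. The 31 members of the 14q32 list have a median of -7.07 in cell RNA and -1.28 in EV RNA, and points between the horizontal axis and the dashed line differ by less in EV RNA.

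The EV to cell difference itself differed between the lines for 69 of 407 miRNAs (41 with a larger value in HepG2 and 28 with a smaller one, and 101 at an unadjusted p under 0.05). In TMM-scaled CPM, miR-148a-3p was lower in EVs than in cells of HepG2, at 136289 ± 2239 against 333581 ± 85382 CPM. It was higher in EVs than in cells of LX2, at 24311 ± 5758 against 54.8 ± 32.7 CPM (difference of the log2 fold changes -10.14, SE 1.03, adjusted p = 1.19e-07 by edgeR). The fall in HepG2 depended on the scaling. As a share of miRNA counts, miR-148a-3p took 11.7% of EVs and 18.3% of cells in HepG2 alone, but 18.6% and 15.8% beside LX2. In TMM-scaled CPM the same directions held for miR-224-5p (-9.44, SE 1.24), while miR-122-5p was higher in EVs of both lines and by less in HepG2 (-7.84, SE 1.85). miR-127-3p stood at 870.3 ± 809 CPM in HepG2 EVs against 1.73 ± 1.44 CPM in HepG2 cells, and at 1389 ± 66.8 CPM in LX2 EVs against 3891 ± 1203 CPM in LX2 cells (10.18, SE 1.16, adjusted p = 3.56e-07). miR-493-5p (8.36, SE 0.995), miR-409-3p (7.74, SE 0.965), miR-411-5p (7.47, SE 1.16) and miR-493-3p (7.41, SE 1.21) differed likewise. In the 14q32 list 21 of 31 members had a larger EV to cell value in HepG2 (22 adjusted over the list alone; median 5.99, and 6.12 at the floor; camera adjusted p = 1.71e-21, adjusted p = 0.0771 with an estimated correlation). In the hepatocyte and epithelial list 10 of 13 had a smaller one (11 adjusted over the list alone; median -6.23, and -5.66 at the floor; adjusted p = 2.51e-05, adjusted p = 0.360 with an estimated correlation). With library sizes from both tables the split was 70 and 16, the stricter filter gave 34, limma 112, and leaving out the cell library of HepG2 or LX2 grown alone 39 and 40. No other small RNA passed this test by edgeR (191 at an unadjusted p under 0.05), while DESeq2 called 131, limma 8 and edgeR with total counts 86.

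Co-culture gave no change shared by both lines and compartments. By edgeR 0 of 407 miRNAs and 0 of 743 other small RNAs passed (28 and 74 at an unadjusted p under 0.05, smallest adjusted p = 0.316 and 0.433), as by DESeq2 and limma, each with 0. In simulated data of this design the test found 32 of 50 miRNAs changed 4-fold in all 4 pairs and 10 of 50 changed 2-fold. The hepatocyte and epithelial list and the fibrosis list had no called member (camera adjusted p = 0.0424 for each, adjusted p = 0.556 with an estimated correlation), with 1 member of the former higher adjusted over the list alone, and 1 of the blood list lower.

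Within each line and compartment 1 library stood against 1, so these ratios carry counting intervals and no test. In HepG2 cells miR-122-5p had 244 counts alone and 11499 beside LX2, a log2 ratio of 5.19 (95% counting interval 5.01 to 5.38), and miR-10b-5p 394 and 14063 counts, a log2 ratio of 4.79. miR-483-3p (3.92), miR-483-5p (2.97) and miR-126-3p (2.71) also had higher levels beside LX2, and miR-584-5p (-4.03), miR-582-3p (-2.12), miR-149-5p (-2.08), miR-1257 (-1.87) and miR-625-3p (-1.86) lower ones. In HepG2 EVs miR-122-5p went the other way, from 35220.0 counts alone to 895 (log2 ratio -4.86). It was followed by miR-543 (-4.15), miR-1468-5p (-3.70), miR-486-5p (-3.04) and miR-412-5p (-3.01), and the highest ratio was 1.47 for miR-221-3p. In LX2 cells the highest ratios were those of miR-3613-5p (4.26), miR-32-5p (4.19), miR-374a-3p (3.87), miR-19a-3p (3.42) and miR-542-3p (2.86), and the lowest that of miR-296-3p (-1.97). In LX2 EVs miR-146a-5p (2.89), miR-194-5p (2.80), miR-224-5p (2.58), miR-192-5p (2.04) and miR-23a-3p (1.42) had higher levels beside HepG2, and miR-1468-5p (-2.42), miR-486-5p (-2.03), miR-122-5p (-2.01), miR-412-5p (-1.43) and miR-10b-5p (-1.30) lower ones. Among miRNAs with 100 counts or more in 1 of the 2 libraries, the numbers at least 4-fold higher and lower were 5 and 3 of 182 in HepG2 cells, 0 and 9 of 71 in HepG2 EVs, 14 and 0 of 282 in LX2 cells and 4 and 3 of 102 in LX2 EVs. With total counts they were, in the same order, 7 and 1, 1 and 7, 11 and 5, and 3 and 3.

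**Figure D4:**
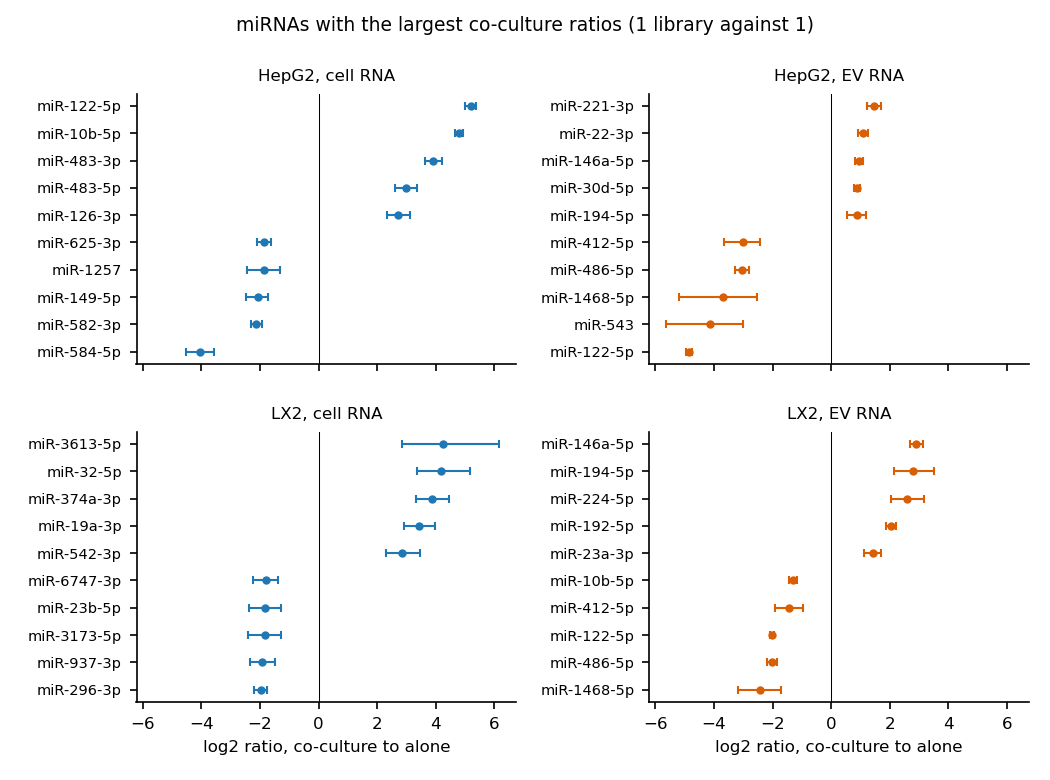
Log2 ratio of co-culture to monoculture (horizontal axis) for the 5 highest and 5 lowest miRNAs with at least 100 counts in 1 of the 2 libraries (vertical axis), in each line and compartment. Points are TMM-scaled ratios of 1 library to 1 and bars their 95% counting intervals; miR-122-5p lies at 5.19 in HepG2 cells and at -4.86 in HepG2 EVs.

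In the 1 pair of LX2 EV libraries, miRNAs of HepG2 mostly stood higher beside HepG2 than alone. Whether the EV library beside HepG2 also held vesicles of HepG2 cannot be told from these data. Ranks among random lists measure the spread between miRNAs and not between cultures, so they do not test this. The 39 miRNAs that were at least 16-fold higher in HepG2 than in LX2 cells grown alone had a median log2 ratio of 2.18 in LX2 EVs, above all of 10000 random lists matched on level (95% of them between -0.03 and 0.86). Of these miRNAs, 13 of the 16 with 10 counts or more were higher, with a median of 1.72, which became 0.70 (18 of 25 higher) for miRNAs chosen at 8-fold and 20 CPM. The hepatocyte and epithelial list gave 1.69 there (percentile 99.97). In HepG2 EVs the miRNAs of LX2 mostly stood lower beside LX2: 4 of the 23 with 10 counts or more were higher (median -1.51, and -0.31 with total counts), and all 61, of which 11 had no count, had a median of 0 (percentile 2.37, 0.36 at 8-fold and 20 CPM and 0 with total counts). In LX2 cells, 8 of the 19 miRNAs specific to HepG2 EVs had no count, and 4 of the 5 with 10 counts or more were higher (median 0.68, but -0.40 at 8-fold and 20 CPM and -0.72 with total counts; all 19 at percentile 3.26). In HepG2 cells, 6 of the 22 specific to LX2 EVs had no count, and 2 of the 6 with 10 counts or more were higher (median -0.62, all 22 at percentile 13.4). With total counts 8 of 18 were higher there, with a median of -0.13. The mesenchymal and stellate list had a median of 0.34 in HepG2 EVs (percentile 94.8) and -0.14 in HepG2 cells (percentile 55.9). With total counts these medians were 1.04 (all tested miRNAs 0.39, percentile 94.6) and 0. In LX2 cells 4 of the 6 members of the hepatocyte and epithelial list with 10 counts or more were higher (median 0.72, all 13 at percentile 14.1).

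The deposited result tables of the authors, which compare EV and cell libraries in the 4 pairs, list 105 of 729 miRNAs at a false discovery rate under 0.05, 47 of them higher in EV RNA, and all 20 miRNAs called here are among these. For other small RNAs they list 623 of 1278 (247 higher in EV RNA), which include 326 of the 332 calls that could be matched by name. Across miRNAs, which are not independent replicates, the fold changes of both analyses correlated with r = 0.999.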

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

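The tests of production by the cells, of carry-over from LX2, of LX2 cells in a cell library, of a common source in the medium, of EV RNA carried into a cell library and of exchanged labels were chosen only after the result was seen. Among 134 groups of 4 values tested, chance alone would place about 1 in 20 this far apart.

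miRNAs of the blood list made up 2.39% of EV miRNA counts and 0.0410% of cell miRNA counts, and 7 of 10 tested members rose in EV RNA. Scaling within the small miRNA share of the EV libraries is argued against, since with library sizes from the sum of both tables all 7 of 7 called members were still higher. Serum in the medium could be 1 outside source, in which case the members would keep fixed proportions over the EV libraries; their spread lay at percentile 17.2 of matched random lists, neither low enough nor high enough to decide. Production by the cells also stays open: 3 members had 3 counts or fewer in the 4 cell libraries together, but rapid export of all copies cannot be told apart from an outside source, and compartment is confounded with the extraction method. Between the lines 1 member was higher and 1 lower in HepG2 cells while none passed in EV RNA, which is too few to decide. No biological explanation beyond production by the cells was tested.

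The lines differed by less in EV RNA than in cell RNA, and 69 miRNAs had an EV to cell difference that itself differed between HepG2 and LX2, led among miRNAs with more than 3 counts in every group by miR-127-3p (10.18, SE 1.16) and miR-148a-3p (-10.14, SE 1.03). Lower depth of the EV libraries is argued against for the size of the 14q32 difference. Cell libraries thinned to the miRNA counts of the EV libraries kept a median log2 fold change of -8.25 for that list (SD 0.470 over 20 draws), against -1.54 in EV RNA. With thinning the mean number of calls between the lines fell to 95.5 from 204 in cell RNA and to 47.8 from 52 in EV RNA. The interaction then gave 32.1 calls on average. Fewer miRNAs were tested (192.85 on average, not 407), so depth may account for part of these call counts. Carry-over of LX2 RNA into the HepG2 EV library is argued against as the only source. There 17 miRNAs of the 14q32 list reached a median of 25.3% of their LX2 EV level (range 0% to 81.4%). For 15 other LX2-specific miRNAs the median was 3.44% (0% to 35.1%), a ratio of medians of 7.37 where carry-over needs values near 1. The ranges overlapped, so single miRNAs of either group do not follow the medians. A medium source common to all EV libraries may contribute: beside LX2 the 14q32 list in HepG2 EVs had a median log2 ratio of -1.05 and the blood list -0.80. The first value met the limit set for a common source and the second missed it. The outcome set against a common source was not met either, so the test does not decide. Selective export by each line stays open and was not tested. Co-culture EV libraries enter these line differences, and vesicles of the partner line in them could not be told apart.

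miR-122-5p was higher in the cells (log2 ratio 5.19) and lower in the EV RNA (-4.86) of HepG2 beside LX2. EV or medium RNA carried into the cell library is argued against, because of the members with large predicted rises miR-486-5p (399.8 CPM predicted) moved by -5.74 CPM, miR-1246 (262.7) by -33.0, miR-451a (34.4) by -5.50 and miR-412-5p (64.3) by 0. Over 15 such miRNAs enriched in EV RNA of both monocultures the median rise was 0% of the predicted one, a value set by members near 0 counts, while miR-10b-5p (3470.0%), miR-126-5p (366%) and miR-126-3p (173%) rose by more than predicted. LX2 cells in the HepG2 cell library are argued against by their own low level of miR-122-5p. It took 0.00188% of miRNA counts in LX2 cells alone and 0.000317% beside HepG2, less than the 0.0104% of HepG2 cells alone. The LX2-specific miRNAs did not rise either, with a median log2 ratio of -0.23 over 19 miRNAs. Exchanged labels of the HepG2 cell libraries may account for opposite signs: across miRNAs the co-culture ratios of HepG2 cells correlated with r = -0.44 with those of HepG2 EVs and -0.312 with those of LX2 EVs (LX2 cells and EVs 0.227), but with 0.341 with those of LX2 cells, which an exchange would turn negative, so with 1 library per condition an exchange cannot be told apart from a response of HepG2 to co-culture.

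The miRNA count of the cell library of LX2 beside HepG2, 3782030, lay far above those of the other 3 cell libraries, 2343737 to 2427218. snRNA made up 1.04% (95% interval 1.02% to 1.06%) of the EV library of LX2 alone and 15.1% ± 1.32 of the other EV libraries, and 0.472% (0.466% to 0.478%) of the cell library of HepG2 alone and 0.202% ± 0.00877 of the other cell libraries. miR-423-5p took 9.22% (9.06% to 9.38%) of the miRNA counts of HepG2 EVs grown alone and 2.05% ± 0.396 in the other EV libraries. In cell RNA, miR-451a stood at 5.50 CPM (2.02 to 11.96) in HepG2 alone and at a mean of 0.303 CPM in the others. miR-144-3p was seen only in HepG2 beside LX2 among the cell libraries, at 0.710 CPM (1 count), and miR-150-5p only in LX2 alone, at 0.740 CPM (2 counts). miR-335-3p had 0 counts in EVs of HepG2 beside LX2, which allows up to 38.9 CPM, and 62.5 ± 4.50 CPM in the other EV libraries.

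Several entries of the EV library of LX2 alone also lay far from the other EV libraries. U1.17 stood at 11.4 CPM (4.57 to 23.4) against 296 ± 18.1 CPM, and SNORD101 at 95.9 CPM (73.0 to 124) against 25.4 ± 3.996 CPM. SNORD88B stood at 4.88 CPM (3 counts) and SNORD121B at 1.63 CPM (1 count), with 0 in the other EV libraries. In the cell library of LX2 alone U1.17 stood at 0.410 CPM (2 counts) and in the other cell libraries at 1.59 ± 0.0458 CPM.

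The deposited reads of putative miRNAs, which no comparison used, hold 1 dominant entry. put-miR-21 (chromosome 2, 19950609 to 19950625, GRCh37) took 199663 reads over the 8 libraries, 75.8% of all putative reads, where a count of 0 would allow 3. It stood at 14403 ± 6268 CPM of the TPM total in EV RNA and 1947 ± 1683 in cell RNA (mean ± SD, n = 4).

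Other ways of splitting the samples were counted for each model. Without pairing, 1 of the 35 splits, the real one, gave as many other small RNAs as EV against cell RNA (334, highest other 15). This excludes chance at a share under 0.05 only for the fit that leaves the pairs aside. For miRNAs without pairing, 2 of the 35 splits gave as many as the real 36, and the highest other, 97, was HepG2 against LX2, which is the structure of the samples, so chance is not excluded. Exchanging compartments within cultures gives 8 splits, too few for a share under 0.05 (miRNA: real 20, highest other 0, and other small RNA: real 337, highest other 0). For the lists 4 of these 8 splits, the real one among them, gave as many called lists as the real 3. The number of called lists was thus matched by splits with exchanged compartments, and chance is not excluded for it. For co-culture the 8 splits are too few as well (miRNA: real 0, highest other 2; other small RNA: real 0, highest other 0).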

How the results depend on the processing

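Alternatives were set before the data were examined except those for other small RNAs between the lines, gene copies summed per family, the EV comparison without the blood and muscle lists, and fry, which were chosen after seeing the data. The EV libraries held as few as 55861 miRNA counts, and in simulated data 13 of 50 features changed 4-fold were found. Where no reason is given with a value, the cause was not tested.

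For miRNAs between EV and cell RNA (20) the count was 33 with total counts, 88 with library sizes from both tables, 121 with DESeq2, 199 with limma on the TPM score, 70 without a filter and 31 under the stricter filter, 116 within HepG2 and 78 within LX2. It was 0 within the monocultures and 0 within the co-cultures, 2 without the blood and muscle lists, which hold 8 of the 20, and 0 to 9 without each culture. The subsets of 1 line, like the monocultures and the co-cultures, hold 2 pairs and leave 1 residual degree of freedom. That alone therefore does not explain the counts of 0. Without pairing by culture 36 were called. For named miRNAs of this comparison 225 alternative values kept direction and side of the threshold, 122 no longer passed it, 15 newly passed it, and those of miR-16-5p, not called, turned to -0.27 with both tables and -1.36 with limma.

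For other small RNAs between EV and cell RNA (337) the count was 564 without a filter, where more entries are tested, 146 within the monocultures and 169 with copies summed (183 with DESeq2 size factors, 231 with total counts), where fewer are tested, and 246 to 413 without each culture; all other settings stayed within 1.5 times, and 353 of 356 values of named entries kept direction and side. The tRNA difference fell to 1.29 points and the piRNA difference to 0.000347 points with all mapped reads as the base, neither past the threshold. Leaving out each culture, the class differences (share of miRNA and small RNA counts, in points) ranged over -43.1 to -31.1 for miRNA, -16.0 to -10.5 for snoRNA, 9.61 to 14.8 for snRNA, 24.4 to 47.0 for tRNA, 0.0356 to 0.0718 for piRNA and 1.63 to 3.70 for Y RNA, where 3 against 3 cannot give a p under 0.1.

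Between the lines in cell RNA (204) the stricter filter gave 84, with fewer miRNAs tested, and leaving out each library 91 to 252, 91 to 118 of these without a cell library. In EV RNA (52) the stricter filter gave 34, limma 96, the 4 EV libraries alone 4 and leaving out each library 1 to 55, with 1 without the EV library of HepG2 alone and 28 without that of LX2 alone. For the interaction (69) the stricter filter gave 34, limma 112 and leaving out each library 39 to 66, with 39 and 40 without the cell library of HepG2 or LX2 alone; miR-382-3p, at 8.17, ranged from -1.38 to 10.93 and turned without the EV library of HepG2 alone, which leaves its group 1 library. Other small RNAs in cell RNA (208) numbered 462 without a filter, 94 under the stricter one and 110 to 276 with a library left out, with 110 and 121 without the cell library of HepG2 or LX2 alone. In EV RNA (0) they numbered 31 with DESeq2, 122 with limma, 42 without a filter, 2 under the stricter one and 0 to 37 with a library left out, and for the interaction (0) 131, 8, 40 and 39, with 86 under total counts and 0 to 27. Co-culture gave 0 under every other setting, but 0 to 2 miRNAs and 0 to 14 other small RNAs with a library left out, the 14 without the cell library of HepG2 beside LX2. For named miRNAs 567 values kept direction and side in cell RNA and 14 no longer passed, against 360 and 107 in EV RNA and 312 and 24 for the interaction. For other small RNAs in cell RNA these were 298 and 15. A lone library left in a group is assumed to vary like the others.

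The 3 called lists became 0 with an estimated correlation, 1 with total counts, 1 with fry, and 2 to 2 without each culture, and 52 values per list kept their side while 11 no longer passed. With total counts the numbers beyond 4-fold became 1 lower in HepG2 cells, 1 higher in HepG2 EVs and 5 lower in LX2 cells, and 26 of 40 named ratios stayed within their counting interval. The partner median of 2.18 became 1.85 at 8-fold and 20 CPM, but over miRNAs with 10 counts or more 1.72 (13 of 16 higher) became 0.70 (18 of 25 higher). Against the fitted median of all miRNAs, total counts moved line differences by -0.96 in cells and -0.65 in EVs, the interaction by 0.36 and co-culture by 0.12, and both tables by -1.53, 0.12, 1.71 and -0.16. For other small RNAs total counts moved cells by -1.05, the interaction by 0.97 and co-culture by -0.55.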

Other observations

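Counts of the imprinted regions were summed, and the test of outside RNA was chosen, only after the values had been seen. snoRNAs of the 15q11 region, which LX2 cells hardly hold (0 counts alone, which allows up to 1.89 CPM of the small RNA total, and 2 counts beside HepG2), stood at 3.30 CPM (95% interval 0.681 to 9.65) in EVs of LX2 alone and at 158 CPM (134 to 184) in EVs of LX2 beside HepG2. In HepG2 they stood at 769 CPM in cells alone and 743 beside LX2, and in HepG2 EVs at 178 alone and 2024 beside LX2.

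The 14q32 miRNAs and snoRNAs were both closer between the lines in EVs than in cells of the monocultures. The miRNAs made up 85.8 CPM of the miRNA total of HepG2 cells alone and 1551 of the 123194 miRNA counts of their EVs (11975 to 13228 CPM), against 73009 CPM in cells and 50204 CPM in EVs of LX2 alone. The snoRNAs of the region made up 39.6 CPM of the small RNA total of HepG2 cells alone and 16.7 CPM (7.22 to 32.9) in their EVs, against 23805 in cells and 646 (595 to 701) in EVs of LX2 alone. Beside LX2, HepG2 cells held 108 CPM of these miRNAs and their EVs 7662, and of these snoRNAs the cells held 6.42 CPM (4.30 to 9.22) and the EVs 32.9 (14.2 to 64.8), from 8 counts.

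Among lists with 5 or more tested members, the medians of co-culture ratios more than 0.5 from 0 that no other part gives came from 1 library against 1 and carry no test. On the log2 scale they were 0.59 for let-7 in HepG2 cells (all tested miRNAs -0.18). In HepG2 EVs they were -0.66 for let-7, 0.77 for the miR-30 family and -1.06 for the miRNAs that overlap structural RNA (all tested 0). In LX2 cells they were 1.22 for the miR-17-92 list, 1.05 for the miR-30 family and -0.62 for let-7 (all tested -0.31). In LX2 EVs they were 2.15 for the structural RNA list, 0.77 for the fibrosis list, 0.69 for the miR-30 family, -0.51 for let-7 and -0.96 for the blood list (all tested 0.37).

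A hypothesis drawn from these ratios is that EV RNA of monocultures holds more RNA of outside origin than that of co-cultures. miRNAs at least 16-fold higher in EV than in cell RNA were chosen in the monoculture of the other line. In HepG2 EVs 19 of 22 such miRNAs were lower beside LX2 (median -0.93), and in LX2 EVs 29 of 43 beside HepG2 (median -0.55). Both medians lay at percentile 0 of matched random lists, but the hypothesis was prompted by ratios in this same set, so this restates them and decides nothing. The hypothesis stays open, and it may also be that the cells release more RNA of their own when cultured together, which was not tested.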
